A study of Homo sapiens with 4 samples.

How the data were processed

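Total RNA of THP-1 cells, 1 sample in each of 4 groups, was measured on Affymetrix arrays. Per the labels' protocols, 300 ng of RNA per sample was converted to cDNA with random primers, amplified and labelled. The deposited values are log2 signals per probe set, which per the submitters' processing notes came from Affymetrix Expression Console 1.1 and RMA, a method that corrects background, normalizes quantiles and summarises probes by median polish. Settings of that step, the annotation library and a genome build were not given in the sources used here. Scanner images and raw intensities were not used here. RMA forces the arrays towards a common distribution, so a shift of most genes in 1 direction would not be visible in these values.

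The table held 53617 probe sets on 4 arrays. Of these, 16098 were paired with 1 gene symbol by the platform annotation used, 0 with several, and 37519 had no name here and were left out of gene counts. All 16098 gene identifiers were found in the RefSeq gene table of assembly GRCh38.p14, which was used for names only, and 0 symbols needed an update. A gene was represented by its probe set with the highest mean over the 4 arrays, which left 14884 genes, 779 of them with more than 1 probe set. No filter on level was applied.

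Groups were taken from the sample titles and treatment tags. Differences were log2 values of the first named array minus those of the second, and a gene was counted at 2-fold or more, the threshold of the series design. Comparisons of the control labelled positive and of both plasma exposures with the control labelled negative come from that design, and the comparison of 3 min with 1 min from the exposure times. With 1 array per group no test was made and no p-value is given. The comparisons of both plasma arrays with the array labelled positive control and the groups of genes by shared start of the symbol were added after the data were seen.

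The comparisons, the named-gene rule, the gene lists and the alternatives listed in this paragraph and the next were fixed before the data were examined, apart from those added comparisons. For each comparison the genes named were the 8 highest and 8 lowest by log2 difference among genes whose brighter array was at or above 5.45, the median log2 level of gene-named probe sets. Small and noncoding RNA, receptor segment and locus-style symbols were left out of that choice. From each list up to 2 members higher and 2 lower with the largest differences past 2-fold, or past 1.5-fold where none passed 2-fold, could be named, or else the member with the largest difference. TNF, IL1B, IL6, CXCL8, CD14, CD68, ITGAM, MMP9, CYBB, SOD2, HMOX1, CDKN1A and MYC were to be named always. IL1B, IL6, ITGAM, MMP9, CYBB, SOD2 and CDKN1A had no named probe set here and are not reported, and the text gives a selection of the genes the rule allows.

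There were 36 gene lists with 987 entries, of which 531 had a named probe set. The lists of replication-dependent histones and of mitochondrially encoded genes had 0 named members. For each of the 31 lists with at least 5 named members, the median log2 difference was given its percentile among 10000 random lists of the same size, matched on mean level in 20 bins. These percentiles describe the 4 arrays and say nothing of replicate error. Alternatives were cyclic loess between arrays with 3 iterations, median centring, removal of genes below the 25th or 50th percentile of mean level, the mean over a gene's probe sets, its dimmest probe set, every probe set counted on its own, removal of noncoding and locus-style symbols, thresholds of 1.5-fold and 3-fold, and random lists not matched on level.

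For overlaps between comparisons that share a control, 100 sets of unchanged arrays were simulated with a noise SD of 0.185 per array, taken from the 3 min minus 1 min difference, and 100 more with an SD for each gene taken from its own 3 min minus 1 min difference, added after the data were seen. No background level was given in the sources used here. A level below the median of all probe sets on its array was therefore raised to that median for a fold, which is printed as a lower bound, a rule also added after the data were seen. The counting step was tested on simulated data for the comparison of 3 min with 1 min over 14884 genes. It called 7.46% of genes changed 1.5-fold, 89.6% of those changed 2.5-fold and 100% of those changed 4-fold, and 2 of 14684 unchanged genes. Of unchanged lists of 20 genes, checked on the noise of 1 simulated array, 5% lay outside the central 95% of random lists. Noise in both checks was equal for all genes and independent between them. Neither check therefore covers noisier genes or lists of genes that vary together. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.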

Results

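Gene expression was measured by array in THP-1 cells, a human monocytic leukaemia line that takes on macrophage features when treated with a phorbol ester. The sample labelled positive control carried no treatment tag, while the sample labelled negative control was tagged with phorbol alone. The other 2 samples were tagged with phorbol and non-thermal plasma, a partly ionised gas that gives off reactive oxygen and nitrogen species, for 1 min or for 3 min. Per the labels, phorbol was given at 100 ng/ml for 2 days ahead of the plasma. Each of the 4 groups had 1 array, so no difference could be set against a replicate error and no test was possible. The small number of arrays limits the precision of every value.

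Gene-named probe sets covered 14884 genes, and the median of all probe sets on an array lay between 4.42 and 4.48 on the log2 scale. The array labelled negative control stood apart from the other 3. Its Pearson correlation across genes was 0.915 with the array labelled positive control, 0.915 with the 1 min plasma array and 0.920 with the 3 min plasma array. Among the other 3 arrays the correlations were 0.988 to 0.991. Genes are not independent replicates, so these correlations carry no p-value. Because these values bear on the labels of the controls, both are called here by their labels, and every direction against either of them follows the label as deposited. Folds against a level below the median of all probe sets on its array are given as lower bounds, with that level raised to the median.

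The series design names a comparison between the 2 controls. On the array labelled positive control, chemokines, macrophage markers and lysosomal genes read higher than on the array labelled negative control, while genes of myeloid precursors, the cell cycle and cholesterol synthesis read lower. CCL2, which attracts monocytes, had a log2 level of 12.76 against 3.89, at least 317-fold higher. The neutrophil attractants CXCL8 and CXCL5 were at least 209-fold and at least 194-fold higher, and TNF, a central inflammatory cytokine, was 26.6-fold higher. Genes at least 2-fold higher numbered 687 and genes at least 2-fold lower 1233, together 12.9% of the genes measured, and 239 and 180 passed 4-fold.

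Among inflammatory cytokines and chemokines, 13 of 23 named members were at least 2-fold higher and 1 was lower, with a median log2 difference of 1.60. CCL20, a chemokine of lymphocytes and dendritic cells, was 114-fold higher, and CXCL10, an interferon-induced chemokine, was at least 4.68-fold lower. NF-kappa B target genes had 8 of 16 members at least 2-fold higher and a median of 1.21. They included BCL2A1, which restrains apoptosis and was at least 94.1-fold higher, and the prostaglandin synthase PTGS2, 78.0-fold higher. The list of protein kinase C and phorbol-related genes had 9 named members, which did not include the protein kinase C genes themselves. Of these members, 7 were at least 2-fold higher, with a median of 2.42. Their examples were the MAP kinase phosphatase DUSP6 at 12.1-fold higher and IER3 at 18.7-fold higher. Immediate early genes, which respond early to stimuli, had 11 of 25 members at least 2-fold higher and a median of 0.68. DUSP1 was 23.9-fold higher, and the proto-oncogene MYC was the 1 member at least 2-fold lower, at 3.17-fold.

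Macrophage differentiation markers were above 0 in 21 of 21 members and at least 2-fold higher in 13, with a median of 1.47. FN1, which encodes fibronectin, was 157-fold higher, SPP1, which encodes osteopontin, at least 37.2-fold higher, and CD14, a coreceptor for lipopolysaccharide, 24.8-fold higher. CD68, a lysosomal marker of macrophages, differed less, at 12.16 against 11.40. Lysosome and cathepsin genes had 10 of 18 members at least 2-fold higher and a median of 1.30, among them the proteases CTSL at 9.34-fold and CTSD at 7.65-fold. The integrin and adhesion list, whose named members did not include the integrins themselves, had a median of 1.46. Of its 12 named adhesion genes, 7 were at least 2-fold higher, ICAM1 among them at 16.4-fold. Matrix metalloproteinases and their inhibitors had a median of 1.01, with 7 of 14 at least 2-fold higher. The neutrophil collagenase MMP8 was at least 28.7-fold and the membrane-bound MMP14 14.8-fold higher. Pattern recognition genes had a median of 0.78, with 10 of 20 at least 2-fold higher and 2 lower. The osteoclast and giant cell fusion gene DCSTAMP was at least 65.0-fold and the protease inhibitor TFPI2 239-fold higher.

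Monocyte and myeloid precursor genes had the lowest median of the lists compared between the controls, at -1.66, with 10 of 19 members at least 2-fold lower and 0 higher. The granule proteases CTSG and PRTN3 were 92.1-fold and 74.0-fold lower, the granule protein AZU1 26.8-fold lower, and MYB, a transcription factor of blood progenitors, 65.1-fold lower. IRF8, a transcription factor of the monocyte lineage, was 36.2-fold lower. Of 35 mitotic and cell cycle genes, 18 were at least 2-fold lower, with a median of -1.003, among them the checkpoint kinase BUB1 at 3.34-fold and the kinesin KIF20A at 3.35-fold. The 1 member that was higher past 2-fold was CCND1, which encodes cyclin D1, at 8.53-fold. DNA replication genes had 7 of 19 members at least 2-fold lower and a median of -0.92, among them the licensing factor CDT1 at 4.05-fold. Cholesterol and SREBP genes had 12 of 21 members at least 2-fold lower and a median of -1.07. The fatty acid enzymes SCD and FASN were 5.72-fold and 5.66-fold lower, whereas SQLE, of the sterol pathway, was 3.16-fold higher. All 26 named ribosomal protein genes were below 0, with a median of -0.86.

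Smaller list medians between the controls were 0.82 for cholesterol efflux and lipid droplet genes, 0.44 for interferon-stimulated genes, 0.39 for NRF2 antioxidant genes, 0.31 for M2-associated markers and 0.26 for hypoxia and glycolysis genes. Interferon-stimulated genes had 7 of 31 members at least 2-fold higher, IFIT3 among them at 5.37-fold, and IFITM1 at 2.24-fold lower. The oxidative stress enzyme HMOX1, which degrades haem, was 3.31-fold higher, and CAT, which encodes catalase, had a log2 difference of -2.07. Apoptosis regulators had a median of 0.25 and a mean of -0.08, with BCL2, a survival gene, 10.0-fold lower. Medians of 0.28 for p53 targets, 0.19 for M1-associated markers, 0.14 for the unfolded protein and integrated stress response, -0.14 for reactive oxygen and nitrogen enzymes and -0.59 for nuclear-encoded respiratory chain genes lay within the central 95% of random lists. So did those of heat shock genes (0.04, mean -0.12) and metallothioneins (-0.11, mean 0.10). Among markers of other cell types, medians were 0.26 for T and NK cells, 0.23 for B cells, 0.28 for erythroid cells and megakaryocytes (mean 1.07, with the platelet chemokine PPBP at least 13.4-fold higher) and 0.21 for epithelium (mean -0.12), also within that range. CTSS, the sole named member of the MHC class II list, was 3.04-fold higher, and with 4 named members each the MHC class I list had a median of 0.54 and the fibroblast list of 0.18. Of the 31 lists with at least 5 named members, 15 lay above and 5 below the central 95% of matched random lists, where 1.55 outside would match chance for unrelated lists. The M1-associated, M2-associated, apoptosis, p53, hypoxia, unfolded protein, respiratory chain and T and NK cell lists lay on the other side of the edge of that range under at least 1 alternative. The lists share members, so these counts are not independent.

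**Figure D1:**
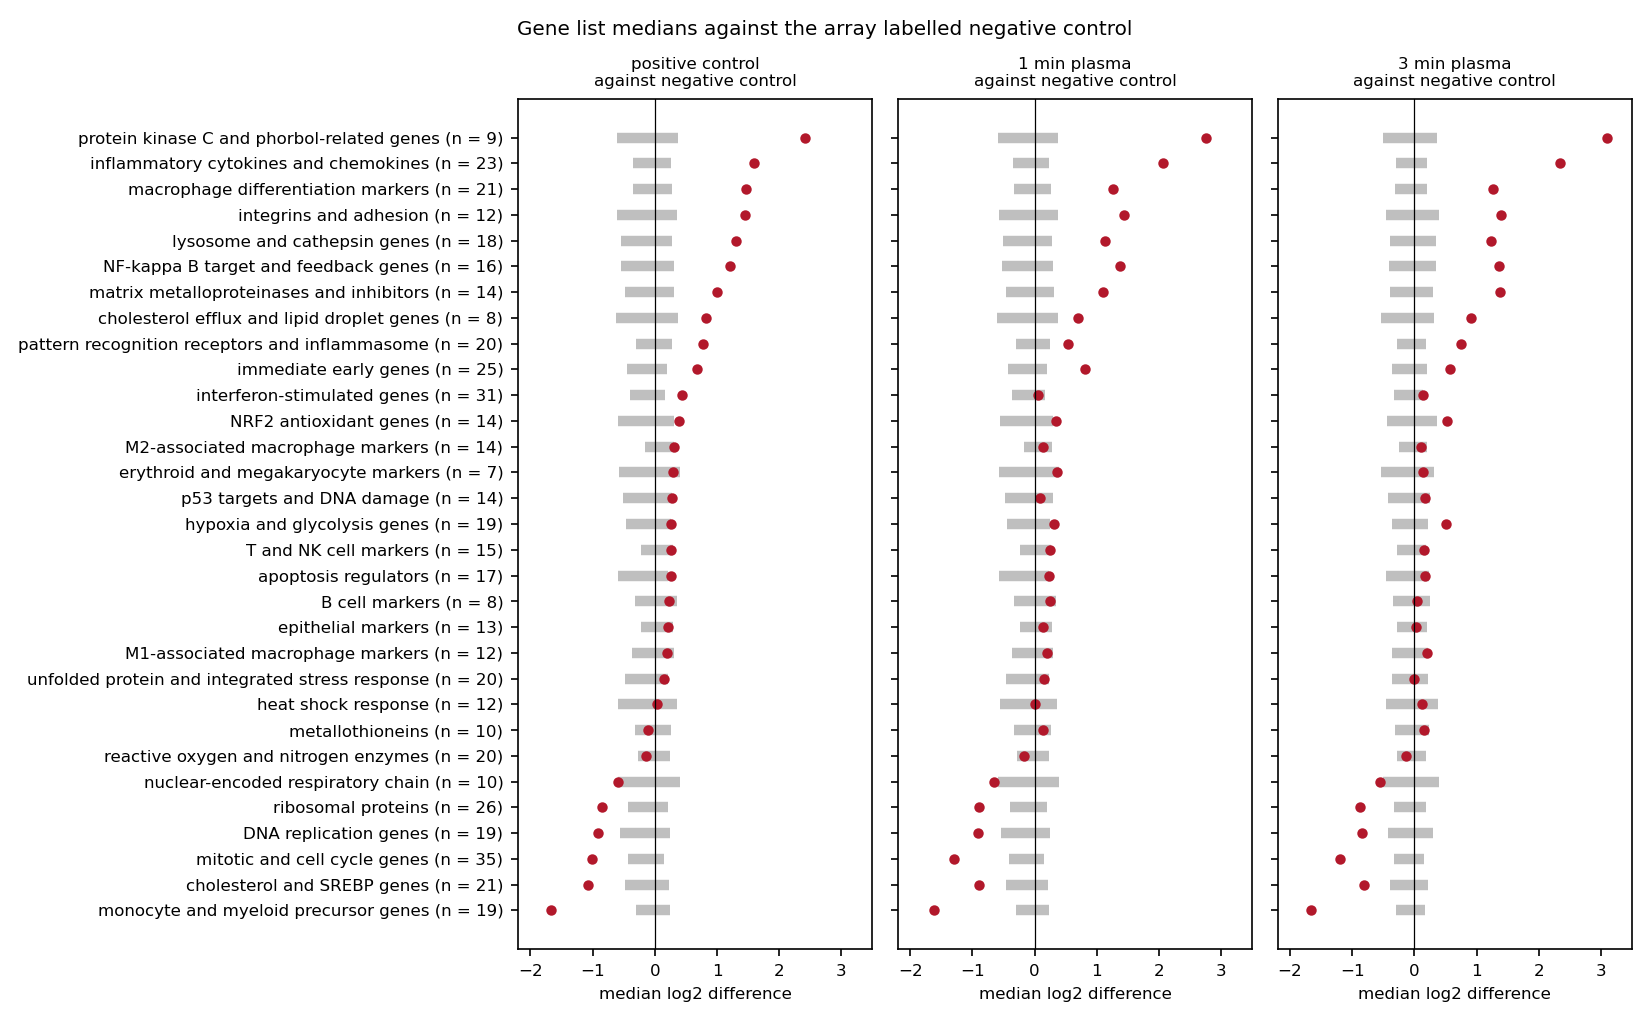
Median log2 difference of each gene list on the array labelled positive control and on both plasma arrays, against the array labelled negative control. Points are list medians, grey bars are the central 95% of medians of 10000 random lists matched on level, and n is the number of named members. The precursor list lies at -1.66, -1.62 and -1.66 in the 3 panels, and the cytokine list at 1.60, 2.06 and 2.34.

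The series design also sets each plasma exposure against the array labelled negative control. Cytokine, macrophage, precursor and mitotic genes differed on both plasma arrays in the direction in which they differed on the array labelled positive control. Inflammatory cytokines and chemokines had a median of 2.06 after 1 min and 2.34 after 3 min, with 14 and 14 of 23 members at least 2-fold higher. CCL2 was at least 392-fold and at least 411-fold higher, CXCL5 at least 316-fold and at least 334-fold, CXCL8 at least 253-fold and at least 265-fold, and TNF 34.1-fold and 36.2-fold. Genes at least 2-fold higher numbered 695 after 1 min and 759 after 3 min, and genes at least 2-fold lower 1166 and 942.

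Macrophage markers had medians of 1.27 and 1.26 on the 1 min and 3 min arrays, with FN1 145-fold and 155-fold higher and CD14 35.5-fold and 30.7-fold higher. The phorbol-related list, without named protein kinase C genes, had medians of 2.75 and 3.09. Its member DUSP4, a MAP kinase phosphatase, was at least 8.68-fold and at least 9.78-fold higher. Of 14 metalloproteinases and inhibitors, 9 and 9 were at least 2-fold higher, and the interstitial collagenase MMP1 was at least 16.3-fold and at least 24.8-fold higher. PTGS2 was 139.7-fold and 156-fold higher, and PPBP at least 23.3-fold and at least 27.2-fold. MT2A, a metal-binding metallothionein, was 3.64-fold and 4.46-fold higher, while the metallothionein list had medians of 0.13 and 0.15, within the range of random lists.

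Precursor genes had medians of -1.62 and -1.66, with CTSG at least 124-fold and at least 129.6-fold lower and MYB 67.7-fold and 62.5-fold lower. Mitotic genes had medians of -1.29 and -1.20, with 26 and 24 of 35 at least 2-fold lower and KIF20A 5.19-fold and 5.27-fold lower. Cholesterol and SREBP genes had medians of -0.90 and -0.81, with SCD 6.68-fold and 4.70-fold lower. Interferon-stimulated genes had medians of 0.05 and 0.14, within the central 95% of random lists, with 3 and 6 of 31 at least 2-fold higher. With only genes at or above the median level counted, those 2 medians lay above that range. NRF2 antioxidant genes, a response to oxidants, had medians of 0.35 and 0.53, with HMOX1 2.57-fold and 2.96-fold higher.

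At least 2-fold differences in the same direction in both plasma comparisons were found for 640 genes higher and 837 lower, and in opposite directions for 0. Independent lists of these sizes would share 35.4 and 73.8 genes, and simulated unchanged arrays that share the negative control shared 0.01 and 0.02 with equal noise for all genes and 18.6 in each direction with noise set gene by gene. Across genes the 2 sets of differences had a Pearson correlation of 0.945 against 0.501 in the simulation, and a covariance of 0.585 against 0.0344. With a single negative control array the control could not be split. The covariance exceeded the simulated one by 0.5508 here, but by 0.0090 with the array labelled positive control as the shared array. Most of the excess therefore went with the array labelled negative control. From that array the array labelled positive control, which carries no plasma tag, also differed at least 2-fold in 1920 genes.

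**Figure D2:**
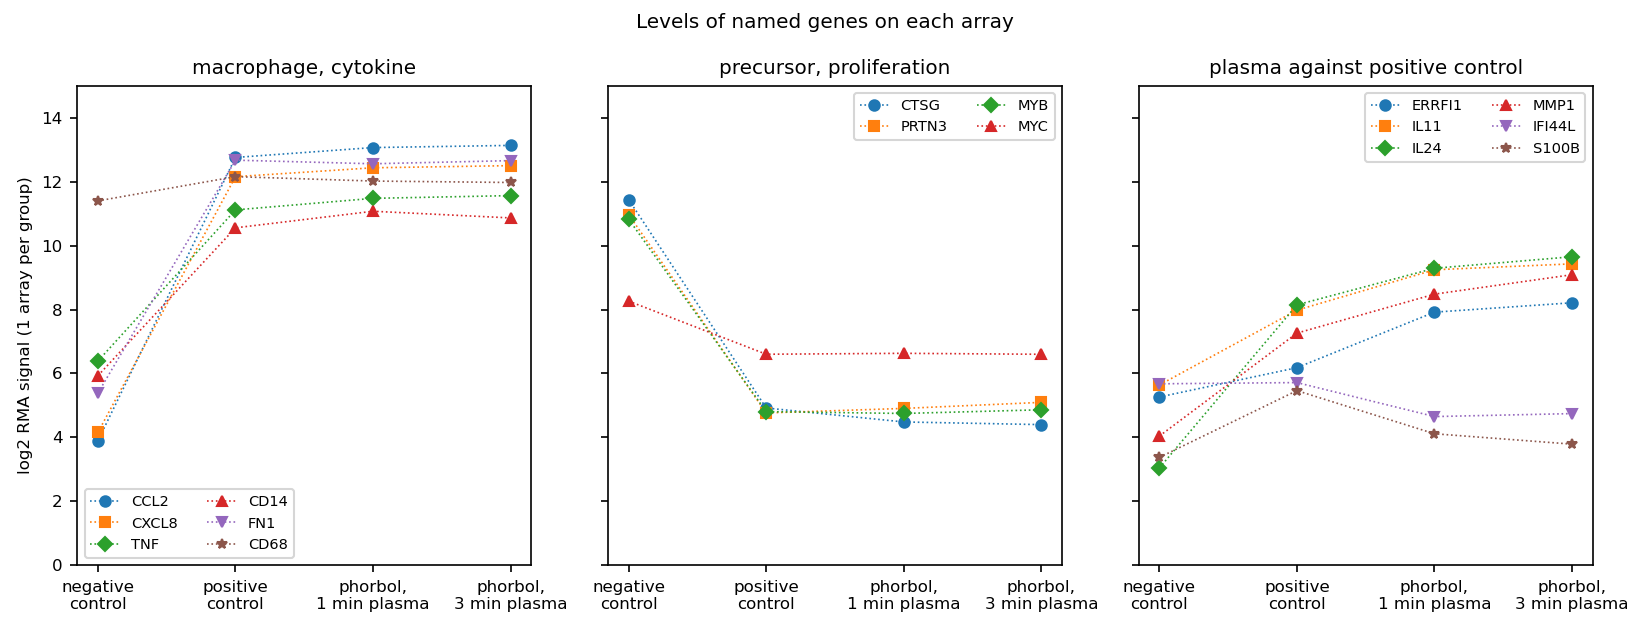
Log2 RMA signal of named genes on the 4 arrays, 1 point per gene and array, with dotted lines that join the points of a gene. CCL2 reads 3.89 on the array labelled negative control and 12.76, 13.07 and 13.14 on the others, and CTSG reads 11.44 there and 4.92, 4.48 and 4.40 on the others.

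The exposure times were then compared directly, without either control. The 3 min array read higher than the 1 min array in HSD17B7, of cholesterol synthesis, by at least 1.22-fold, in the zinc finger genes ZNF836 by at least 2.25-fold and ZNF737 by 2.05-fold, and in the stress kinase gene MAP2K4 by 1.98-fold. It read lower in MEX3A, an RNA-binding protein gene, by 2.13-fold, and in the pseudogenes NF1P2 by 2.61-fold and WASH3P by 2.21-fold. S100A12, a calcium-binding protein of myeloid cells, was 1.83-fold higher. Genes at least 2-fold higher numbered 20 and genes at least 2-fold lower 26, or 0.309% of genes, and 0 passed 4-fold in either direction.

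Inflammatory and macrophage genes differed little between the exposure times. TNF read 11.57 after 3 min and 11.48 after 1 min, CXCL8 12.51 and 12.44, CD14 10.87 and 11.08, CD68 11.98 and 12.02, and HMOX1 6.95 and 6.74. Chemokine CCL4 was 1.54-fold and MMP1 1.52-fold higher after 3 min, the interferon-induced USP18 1.38-fold lower. List medians were 0.09 for cytokines and chemokines, 0.05 for interferon-stimulated genes, 0.01 for macrophage markers and 0.12 for mitotic genes. Genes for p53 targets and DNA damage had the highest median, 0.18, within the central 95% of random lists here and above it under some alternatives. The medians of lysosome genes at -0.03, immediate early genes at -0.03 and DNA replication genes at 0.02 lay below that range. Under the 8 alternatives, immediate early genes lay within it or at its edge in 4, DNA replication genes in 4 and lysosome genes in 1. In total 0 lists lay above the range and 3 below it.

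Across genes, the 3 min minus 1 min difference had a Pearson correlation of -0.129 and a Spearman correlation of -0.208 with the difference between the controls, with which it shares no array. Without noncoding and locus-style symbols the counts were 7 higher and 12 lower, and among genes at or above the median level 1 and 5.

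After the array labelled negative control was seen to stand apart, both plasma arrays were also set against the array labelled positive control. This pair of comparisons was chosen after the data were seen. ERRFI1, a feedback inhibitor of the EGF receptor, was 3.34-fold higher after 1 min and 4.09-fold higher after 3 min. The interleukins IL11 and IL24 were 2.40-fold and 2.21-fold higher after 1 min and 2.73-fold and 2.84-fold after 3 min, and MMP1 2.33-fold and 3.55-fold. S100B, a calcium-binding protein, was at least 1.97-fold and at least 2.05-fold lower, and FCRLA, an Fc receptor-like gene of B cells, 2.36-fold and 2.19-fold lower. Genes at least 2-fold higher numbered 27 after 1 min and 59 after 3 min, and genes at least 2-fold lower 19 and 32.

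Inflammatory cytokines and chemokines had medians of 0.31 and 0.43, above 0 in 19 and 18 of 23 members. The neutrophil chemokine CXCL3 was 1.83-fold and 2.06-fold higher, CXCL8 1.21-fold and 1.27-fold, TNF 1.28-fold and 1.36-fold, PTGS2 1.79-fold and 2.00-fold, and IL10, an anti-inflammatory cytokine, at least 1.37-fold and at least 1.65-fold. Interferon-stimulated genes had medians of -0.31 and -0.28, below 0 in 30 and 29 of 31 members. IFI44L was 2.09-fold and 1.96-fold lower and IFIT3 1.95-fold and 1.72-fold lower. Mitotic and cell cycle genes had medians of -0.28 and -0.17, below 0 in 34 and 28 of 35 members, with the mitotic kinase PLK1 at -0.71 and -0.59. These 3 lists lay outside the central 95% of matched random lists in both comparisons and under every alternative. In all, 3 lists lay above and 4 below that range after 1 min, and 2 and 6 after 3 min.

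Metallothioneins had a median of 0.31 after 1 min, above the range of random lists, and of 0.11 after 3 min, within it, although under 2 of 8 alternatives the 3 min median lay above it and reached 0.42, with MT1X 1.90-fold and 1.90-fold higher. NRF2 antioxidant genes differed little as a list, with medians of -0.00 and 0.07, while their member HMOX1 read lower, at -0.37 and -0.16 on the log2 scale. Heat shock genes had medians of -0.03 and 0.10, and p53 targets of -0.09 and 0.03, all within that range. Macrophage markers had medians of -0.11 and -0.12, below the range, while the lipid scavenger receptor CD36 was 1.31-fold and 1.66-fold higher. The M1-associated list had medians of 0.17 and 0.21, above the range, although its member CD86, a costimulatory receptor, was at least 1.38-fold lower after 1 min. Ribosomal protein genes lay below the range at -0.08 after 1 min and -0.14 after 3 min, and lysosome genes at -0.11 and DNA replication genes at -0.03 after 3 min. The macrophage and M1-associated lists came to lie within the range under at least 1 alternative in each of the 2 comparisons, as did the ribosomal list after 1 min and the lysosome and DNA replication lists after 3 min.

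Past 2-fold in the same direction in both were 17 genes higher and 4 lower, and 0 in opposite directions, where independent lists would share 0.107 and 0.0408 and simulated arrays with a shared control shared 0.02 in each direction with equal noise for all genes. Equal noise leaves out the noisier genes, and with noise set gene by gene, which puts 140.4 genes past 2-fold where 46 were past it between the exposure times, 19.4 and 18.6 were shared. That noise falls on the genes that differ most between the exposure times and overstates the number past 2-fold. The simulation therefore cannot decide whether the 17 and 4 shared genes exceed the overlap of unchanged arrays. The correlation across genes was 0.570 against 0.4999 simulated, and the covariance 0.0434 against 0.0344, a difference of 0.0090. With 1 positive control array the control could not be split here either, so part of any excess may come from that array. Without noncoding and locus-style symbols the counts were 15 higher and 9 lower after 1 min and 33 higher after 3 min. Among genes at or above the median level they were 13 and 5 after 1 min and 27 and 12 after 3 min.

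**Figure D3:**
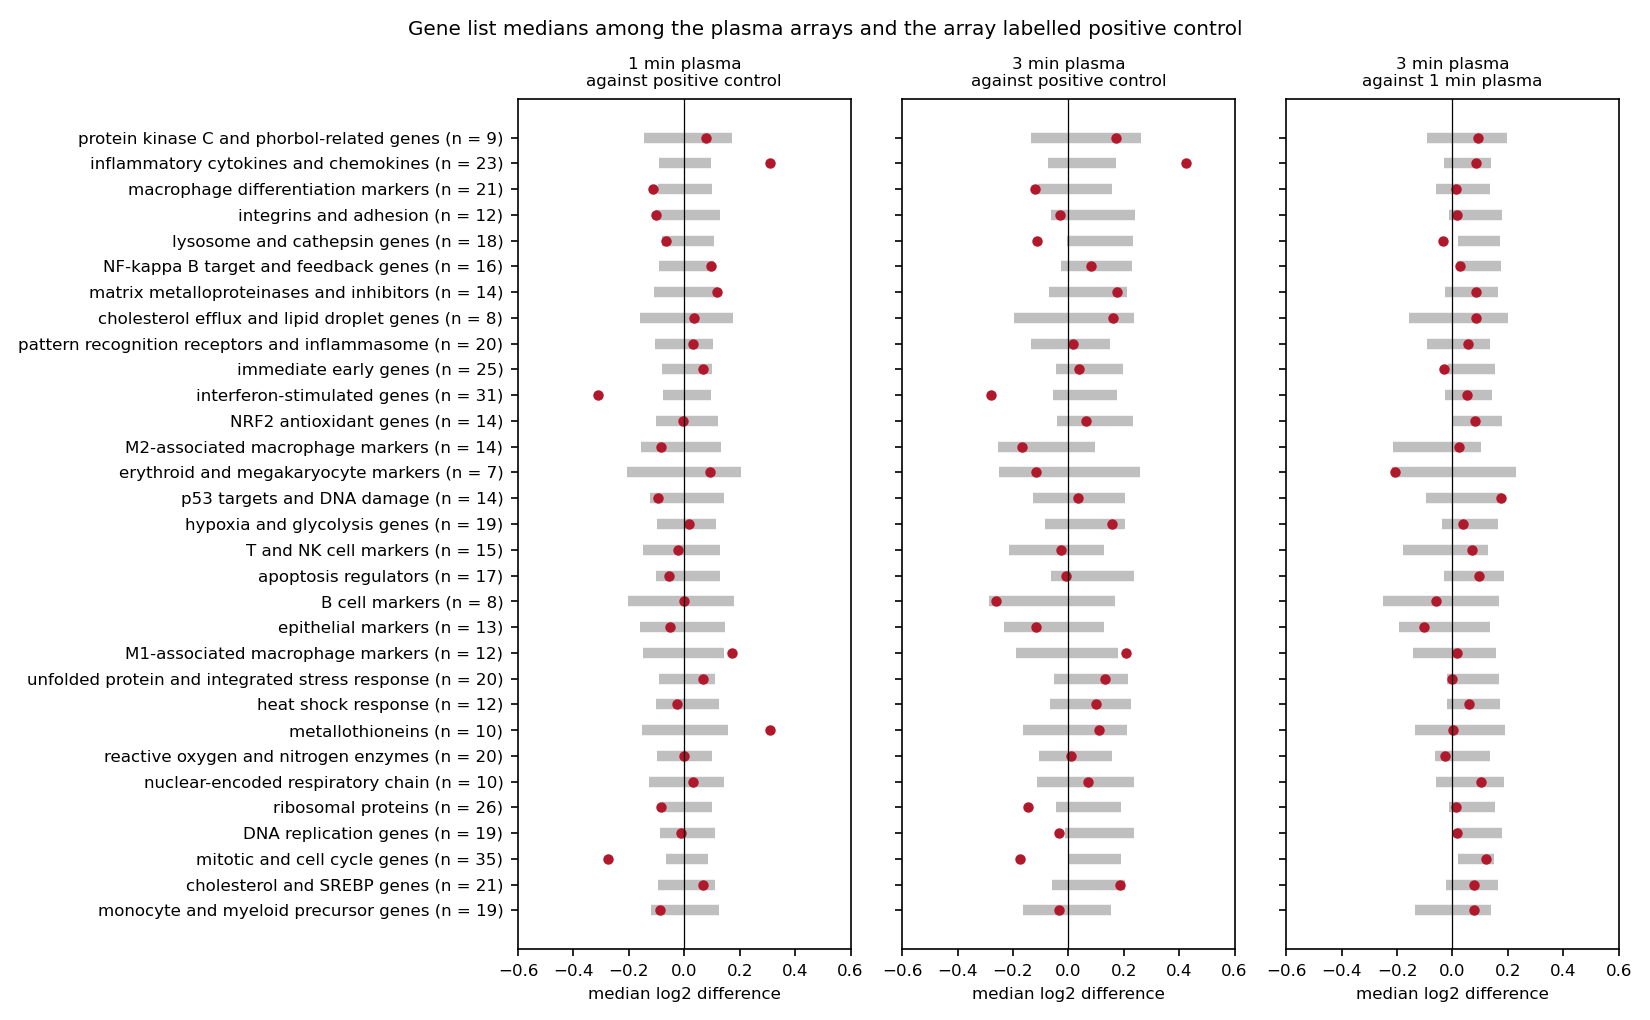
Median log2 difference of each gene list between both plasma arrays and the array labelled positive control, and between the 2 exposure times. Points are list medians, grey bars are the central 95% of medians of 10000 random lists matched on level, and n is the number of named members. Interferon-stimulated genes lie at -0.31 and -0.28, and cytokines and chemokines at 0.31 and 0.43, against the positive control.

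**Figure D4:**
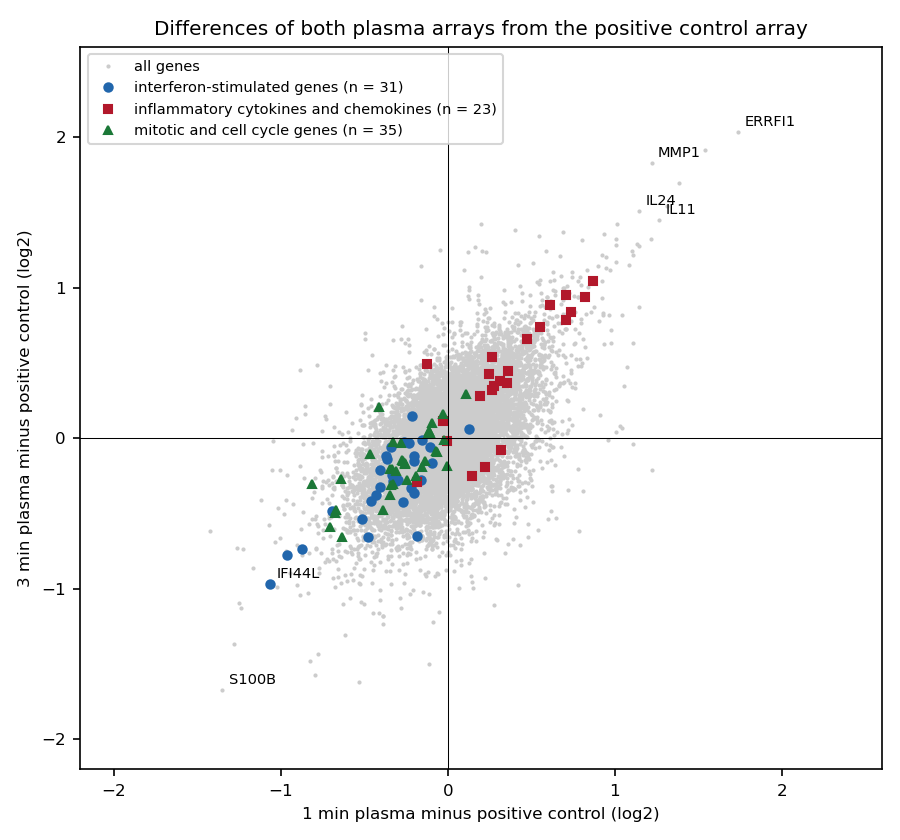
Log2 difference of every gene between the 1 min plasma array (horizontal) or the 3 min plasma array (vertical) and the array labelled positive control, with 1 point per gene and the members of 3 lists coloured. Both axes use the same control array, which tilts the cloud along the diagonal, with a correlation of 0.570 across genes against 0.4999 in simulated unchanged arrays.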

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

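Tests of the phorbol tag, of normalization and of the state of the positive control culture were chosen after the results were seen. So were the comparisons of both plasma arrays with the array labelled positive control. Cyclic loess had been fixed beforehand as an alternative for the planned comparisons.

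Probe sets with no gene name here lay outside the comparisons of genes, and some of them differed between the plasma arrays and the array labelled positive control. After 1 min, 528 were at least 2-fold higher and 228 lower, or 2.02% of the 37519 unnamed probe sets, where 0.309% of genes passed 2-fold. After 3 min, 927 were higher and 309 lower, or 3.29%, where 0.611% of genes did. Between the 2 plasma arrays 687, or 1.83%, also passed 2-fold, a share near that after 1 min and below that after 3 min. The median level of the brighter array among them was 5.29 after 1 min and 5.61 after 3 min, so many were dim, and 46.6% and 54.0% were at or above the median level of gene-named probe sets.

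Macrophage genes read low and myeloid precursor genes high on the array labelled negative control, although its tag names phorbol, which differentiates THP-1 cells. After cyclic loess of the RMA values the macrophage list kept a median log2 difference of 1.45 between the controls, above the -0.27 to 0.29 of random lists. Before loess the median of 1.47 already lay above random lists matched on level, so loess was a weak further check. Both values argue against level-dependent normalization of that array as the whole cause. Other faults of normalization were not tested. A candidate explanation is that the phorbol tag stands on the wrong control, since both plasma arrays, which carry that tag, correlated better with the array labelled positive control, by at least 0.0677. A wrong tag, a phorbol-treated culture that did not differentiate and another sample in its place cannot be told apart, since each control is a single array. The array labelled positive control carries no phorbol tag, yet it correlated at 0.991 and 0.988 with the 1 min and 3 min plasma arrays. A negative control culture that did not differentiate would leave that resemblance unexplained, unless the positive control was also treated, which its labels do not state. If the tag is wrong, differences of the plasma arrays from the array labelled negative control may hold the phorbol response together with any effect of plasma.

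Interferon-stimulated genes read lower on both plasma arrays than on the array labelled positive control. After cyclic loess their median was -0.33 after 1 min, below the -0.09 to 0.08 of random lists. Before loess it already lay below random lists matched on level, at -0.31, so loess was a weak further check. Both values argue against level-dependent normalization as the whole cause. The median difference between 3 min and 1 min was 0.0531, within the -0.03 to 0.14 of random lists, and against the array labelled negative control the list stood at 0.44 on the positive control but at 0.05 and 0.14 on the plasma arrays. A lower interferon response after plasma and a higher one in the single positive control culture cannot be told apart, because no second positive control was measured here.

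Inflammatory cytokines and chemokines read higher on both plasma arrays than on the array labelled positive control. After cyclic loess their median was 0.30 after 1 min, above the -0.10 to 0.09 of random lists. Before loess it already lay above random lists matched on level, at 0.31, so loess was a weak further check. Both values argue against level-dependent normalization as the whole cause. Between 3 min and 1 min the median difference of these cytokines and chemokines was 0.0858, within the -0.03 to 0.14 of random lists. An effect of plasma on these genes and the state of the single positive control culture cannot be told apart with 1 array of each, so the effect remains a hypothesis.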

How the results depend on the processing

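Comparisons of the plasma arrays with the positive control, and their alternatives, were added after the data were seen. Of 147 counts and correlations under the alternatives, 105 kept their direction and stayed within 1.5 times the reported count or 0.1 of the reported correlation, and 42 did not. Cyclic loess, median centring, the mean over probe sets and probe sets on their own moved none past those limits, and cyclic loess moved the median of all genes by at most 0.0246. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out.

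The other counts moved because fewer genes were counted or because the threshold moved. Genes at least 2-fold higher at 3 min than at 1 min numbered 10 above the 25th percentile of level. Above the 50th percentile they numbered 1, with 5 lower, and against the positive control 13 were higher and 5 lower after 1 min, 27 and 12 after 3 min, with 12 shared. Without noncoding and locus-style symbols the counts were 7 and 12 between the exposure times, 15 and 9 for 1 min and 33 higher for 3 min against the positive control, with 11 shared. At 1.5-fold, genes higher and lower numbered 1640 and 2605 between the controls, 1567 and 2537 for 1 min and 1476 and 2228 for 3 min against the negative control, with 3111 shared. At the same threshold they numbered 175 and 317 between the exposure times, and 222 and 208 for 1 min and 422 and 390 for 3 min against the positive control, with 190 shared. At 3-fold, they numbered 365 and 378 between the controls, 355 and 351 for 1 min and 391 and 294 for 3 min against the negative control, with 609 shared. At that threshold 0 and 0 were left between the exposure times, and 1 and 0 for 1 min and 4 and 2 for 3 min against the positive control, with 1 shared.

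Of 1464 list medians under the alternatives, 1373 stayed outside or inside the range of random lists as in a separate run of the main setting. That run drew fewer random lists than the reported percentiles, so lists at the edge could differ. Hypoxia genes between the controls were at percentile 97.00 in it against 97.59 as reported. Metalloproteinases for 1 min against the positive control were at 97.70 against 96.97. For p53 targets at 3 min against 1 min the percentiles were 97.55 and 97.44. Another 52 medians came to lie outside the range and 33 inside it. The other 6 had lain outside it in that run and changed sign. Changes of sign among medians inside the range were not counted. Between the exposure times, the median of DNA replication genes was -0.0438 under cyclic loess, that of lysosome genes 0.0145 under median centring, and that of immediate early genes 0.0186 under median centring and 0.0360 with each probe set on its own. Against the positive control, DNA replication genes had 0.0177 after 3 min under median centring, and metalloproteinases -0.0545 after 1 min above the 50th percentile of level. Median centring moves all genes alike, so the 3 changes of sign under it follow from the shift, and the percentiles among random lists stayed at 0.05 for lysosome, 1.00 for immediate early and 0.9 for DNA replication genes. For the others the cause was not tested. All 425 values of named genes moved by less than 0.262, the SD of the 3 min minus 1 min difference, under cyclic loess and under median centring. Of the 33 values of genes with several probe sets, 19 moved further with the mean over probe sets, and with the dimmest probe set 18 moved further and 2 changed sign, MXI1 between the controls from -1.11 to 0.50 and IRAK3 after 3 min against the negative control from -1.62 to 0.14. Dim probe sets limit the counts between the exposure times, where 1 of 20 higher and 5 of 26 lower genes lay above the 50th percentile of level. Against the positive control 13 of 27 higher and 5 of 19 lower genes did after 1 min, and 27 of 59 and 12 of 32 after 3 min. Those shares are nearer the share of all genes that the filter keeps.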

Other observations

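Groups of genes whose symbols share their leading letters were compared after the data were seen, and those named here were chosen after their values were seen. Zinc finger genes of the ZNF group, many of which encode transcriptional repressors, had a median log2 difference of -0.33 on the array labelled positive control against the array labelled negative control over 476 genes. Of these ZNF genes, 74 were at least 2-fold lower and 3 higher. The ZNF median was -0.31 on the 1 min array and -0.23 on the 3 min array against the negative control, 0.07 at 3 min against 1 min and 0.11 at 3 min against the positive control. Cyclic loess gave 0.09 and 0.12 for the last 2. Of all 169 symbol groups, 7 lay above and 3 below the central 95% of matched random lists at 3 min against 1 min, and 13 and 4 at 3 min against the positive control. By chance 8.45 unrelated groups would lie outside, so a group picked for its value carries little weight there. ZNF genes share similar sequence, so signals of single members are uncertain.

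Between the controls 16 of the 169 symbol groups lay above and 19 below the central 95% of matched random lists, where 8.45 would lie outside by chance for unrelated groups. Genes of centrosomes, DNA repair and nuclear pores read lower on the array labelled positive control than on the array labelled negative control. The CEP group of 38 centrosomal genes had a median of -0.70, with 15 at least 2-fold lower and 0 higher, and the RAD group of 17 genes, many of them in DNA repair, had -0.86, with all 17 below 0. The NUP group of 24 genes, most of them of the nuclear pore, had -0.65. The MRPS group of 26 genes, which encode small-subunit proteins of the mitochondrial ribosome, had -0.52, with 25 below 0. These 4 medians stayed negative under cyclic loess, at -0.59, -0.73, -0.54 and -0.45. The PCDHB group of 19 clustered protocadherin genes, which encode adhesion proteins known mainly from neurons, had -0.71, and DUSP genes, which encode phosphatases that act on MAP kinases among others, had 0.39 over 24 genes, with 7 at least 2-fold higher and 0 lower.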
